A study of Homo sapiens with 22 samples.

How the data were processed

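Droplet 3' single-cell RNA sequencing of 22 skin biopsies (12 SSc, 10 healthy control) was deposited as raw gene by barcode matrices, 1 per biopsy, and each value is a UMI count of the authors' pipeline, per the labels. The reads had been demultiplexed with bcl2fastq and aligned and counted with Cell Ranger 3.0.2 on GRCh38, and cells had been analysed with Seurat 3.0, per the submitters' processing notes. The matrices held 33538 genes, 48 of them with a symbol that another gene shares, and all barcodes, empty ones included, so cells were called anew. All values held whole numbers, and no pair of libraries was identical.

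Barcodes with at least 500 UMIs, at least 300 detected genes and at most 20% of UMIs from mitochondrial genes were kept (53958). The mitochondrial filter removed 0.828% to 11.6% of the barcodes of a control library and 2.57% to 10.9% of those of an SSc library. Doublets were scored against 2 simulated doublets per barcode (2000 variable genes, 30 components) in the manner of Scrublet with own code, and the highest 0.8% per 1000 barcodes were left out of each library. Counts were scaled to 10000 per cell and log-transformed, 3000 variable genes were chosen per library, and 40 principal components were corrected by library with an own implementation of the Harmony method (50 clusters, theta 2, sigma 0.1, lambda 1, 8 rounds). Leiden clusters were found at resolution 1 on a graph of 20 neighbours. A cluster was named "-like" from fixed marker genes when at least 3 of them were detected in at least 10% of its cells at more than 2-fold the other cells. It stayed unnamed if its 10 leading genes held more markers of another class, or if it was shallow and they held none of its own. Sub-clusters of fibroblast-like cells were named by the same rule. Fibroblast-like cells were clustered again (2000 genes, 30 components, resolution 0.8). The share of free RNA in the UMIs of a class was estimated from barcodes under 100 UMIs. It was 4.52% ± 1.60 in control and 4.04% ± 1.35 in SSc fibroblast-like cells, 7.43% ± 4.18 and 11.1% ± 4.46 in keratinocyte-like, 4.00% ± 2.16 and 3.42% ± 1.43 in pericyte and smooth muscle-like, 2.77% ± 0.910 and 3.01% ± 0.697 in blood endothelial-like, 5.64% ± 5.53 and 5.08% ± 6.81 in macrophage and dendritic-like, and 3.87% ± 1.70 and 5.31% ± 3.05 in T and NK-like cells.

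For each class, counts were summed per biopsy (at least 20 cells, at least 3 biopsies per group) and tested with the edgeR quasi-likelihood test with chemistry and group as terms, TMM normalization, edgeR's own filter on low counts and a Benjamini-Hochberg adjusted p below 0.05. Mitochondrial genes, XIST, TSIX and Y-linked genes were left out. Reported CPM are means of the biopsies. Gene lists, 32 in number and fixed beforehand, were tested with camera of limma on log2 CPM (prior count 2, preset correlation 0.01, at least 5 measured genes), adjusted over 137 tests of lists and classes. Shares of cells were compared by 2-sided permutation within chemistry (100000 draws) and by exact permutation within V1 and within V2, and all tests were 2-sided. For shares of fibroblast-like cells with a UMI, cells were thinned to 1000 UMIs, with 500 and 2000 as alternatives. The comparison of cells with and without SFRP4 had biopsy as a block, and that of the SSc effect between SFRP2 and other fibroblast-like cells had biopsy, state and their interaction with group, with at least 10 cells of each kind.

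Groups, tests, filters, lists and markers were chosen before the data were examined, as was the rule for genes named here. That rule took, among genes with an adjusted p below 0.05, at least 10 CPM in a group and one sign in V1 and V2, the 12 largest rises and 12 largest falls in fibroblast-like cells and the 6 and 6 in other classes. Within fibroblast-like cells it took 10 and 10 without the chemistry condition. It added up to 4 genes of smallest p per list and, in fibroblast-like cells, 19 genes by name whatever their p. Immunoglobulin, T cell receptor and HLA genes were not named, and a part of the genes that qualified is given only within the counts. Several of the 19, such as SFRP2, SFRP4, PRSS23, WIF1 and ADAM12, follow what the study named from these samples.

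The pipeline was tested on simulated data. Of 200 genes changed 2-fold and 4-fold, 72.0% and 99.5% were recovered in fibroblast-like, 76.0% and 100.0% in blood endothelial-like, 81.0% and 99.0% in pericyte and smooth muscle-like, 68.5% and 98.5% in macrophage and dendritic-like and 78.5% and 100.0% in T and NK-like sums, and 75.5% and 99.0% for the interaction. In these fits and those of keratinocyte-like sums 4 to 19 unchanged genes were called falsely, with 19 beside the 162 recovered in the 2-fold run of pericyte and smooth muscle-like sums and 16 beside 200 in the 4-fold run of T and NK-like sums. With no difference set, 10 of 200 simulated shares had p under 0.05, and with 10 points 199 of 200. These simulated shares spread less over biopsies than the real shares of 2 large classes. The SD in control and SSc was 14.8 and 9.71 points for fibroblast-like and 10.3 and 14.6 for keratinocyte-like cells. For those classes a difference of 10 points could thus be missed. Alternatives were DESeq2, size factors of the RLE type, no filter on low counts, no chemistry term, each chemistry alone, other minimums of UMIs, mitochondrial share and cells, doublets kept, free RNA subtracted, depth as a term, components without correction, each biopsy left out, another cell calling rule, a logit scale, an estimated correlation and fry. Depth as a term was the median UMIs per cell of the tested class in a biopsy, on a log scale. Counts of UMIs limit the smallest share that can be seen, and limits for a count of 0 cover counting error only. Pseudotime and transcription factor activity were not inferred. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.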

Results

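Droplet-based single-cell RNA sequencing had been run on 22 skin biopsies, 12 from people with systemic sclerosis (SSc, a disease of skin fibrosis and vessel damage) and 10 from healthy controls. The series title names the myofibroblast transcriptome and SFRP2+ fibroblasts, so the comparisons asked which cell classes and genes differed in SSc skin, and how fibroblasts with SFRP2 and SFRP4 transcripts differed from others. Each library was 1 biopsy, so all p-values rest on separate biopsies per the labels, and cells were never counted as replicates. The V1 chemistry had been used for 3 SSc and 6 control libraries and the V2 chemistry for 9 SSc and 4 control libraries. No trait of the donors other than SSc was a term in the tests, so a difference called an effect of SSc may include such traits. A library held 8887763 to 35694424 UMIs (unique transcript molecules) in controls, with a median of 13131382, and 9409516 to 46288473 in SSc, with a median of 20096098.5. The kept barcodes numbered 1162 to 3844 per control library and 1059 to 3840 per SSc library. Their median UMI count per library ran from 1816 to 6161 in controls and from 2972 to 7220 in SSc. After 1173 barcodes scored as doublets were left out, 52785 cells remained. Of these, 46557 lay in 24 clusters that the marker genes named as 1 of 11 classes and 6228 lay in 6 clusters that they did not name.

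Keratinocyte-like cells made up 30.1% ± 14.6 (SD, n = 12) of the cells of SSc biopsies and 19.2% ± 10.3 (n = 10) of those of controls. Fibroblast-like cells made up 16.5% ± 9.71 and 29.2% ± 14.8, pericyte and smooth muscle-like cells 13.6% ± 6.86 and 16.0% ± 6.85, and blood endothelial-like cells 10.0% ± 2.78 and 11.2% ± 5.93. None of these shares passed the test. The difference for fibroblast-like cells was -11.3 percentage points with a standard error of 5.69 (permutation p = 0.0643, adjusted p = 0.523). It was -12.9 points within V1 (exact p = 0.226) and -10.1 within V2 (exact p = 0.158). Pericyte and smooth muscle-like cells differed by 7.30 points within V1 (exact p = 0.119) and by -8.04 within V2 (exact p = 0.0503). Macrophage and dendritic-like cells had means of 4.9999% in SSc and 3.59% in controls, and T and NK-like cells 5.69% and 4.81%. For secretory gland-like cells, which carry sweat gland genes such as DCD, the means were 2.26% and 2.96%. Schwann-like cells had 1.20% and 1.98% (adjusted p = 0.523), with a difference of 0.485 points within V1 (exact p = 0.333) and -1.89 within V2 (exact p = 0.0224). Melanocyte-like cells had 0.779% and 0.773%, mast-like cells 0.459% and 0.456%, and lymphatic endothelial-like cells 0.419% and 0.569%. The 2-sided permutation test of the 11 shares passed none after adjustment, and 0 had an unadjusted p under 0.05. The logit of the share, run as a second scale, also passed 0. Cells of the unnamed clusters made up 13.9% ± 5.93 in SSc and 9.23% ± 3.61 in controls (permutation p = 0.0626). The largest of these clusters was shallow, with a median of 1076 UMIs per cell, and led by HBB and S100A8. Its 10 leading genes held 4 keratinocyte markers, and its cells are not part of the keratinocyte-like share.

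**Figure D1:**
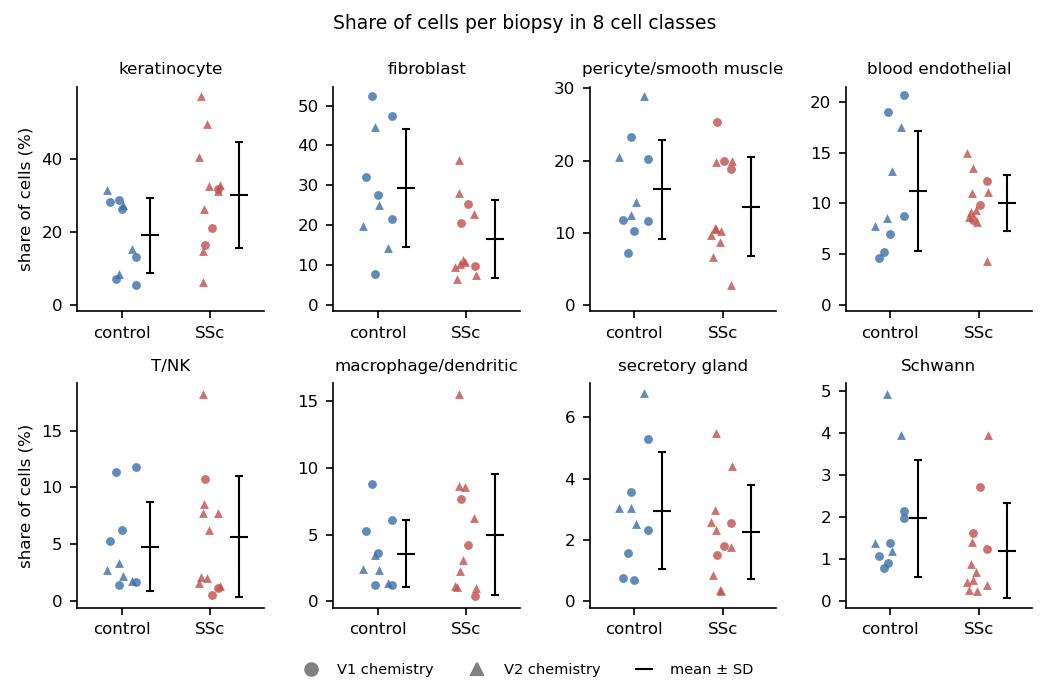
Share of cells (percent, vertical axes) of 8 cell classes in each biopsy of control and SSc skin; each point is 1 biopsy, circles are V1 and triangles V2 libraries, and bars give the mean ± SD (n = 10 and 12). The fibroblast means were 29.2% in control and 16.5% in SSc skin, and no class passed the test.

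Fibroblast-like cells of SSc skin showed 329 genes higher and 185 lower among 9548 tested (edgeR, 12 SSc and 10 control biopsies). PRSS23, a secreted serine protease, rose from 89.6 ± 37.1 CPM (library-scaled counts) to 601 ± 440, a log2 change of 3.01 with a standard error (SE) of 0.47 (adjusted p = 0.00175). It lay above the control mean of its chemistry in 12 of 12 SSc biopsies, with log2 changes of 2.51 within V1 and 3.39 within V2. ADAM12, a membrane metalloprotease, rose by 3.03 (SE 0.44, adjusted p = 0.000244), from 1.14 ± 1.05 to 10.5 ± 5.57 CPM. COL8A1, a short-chain collagen, rose by 2.44 (SE 0.43, adjusted p = 0.00318), and both rose in 11 of 12 SSc biopsies. LEPR, the leptin receptor, fell from 51.1 ± 28.99 to 13.04 ± 7.63 CPM (log2 -2.28, SE 0.28, adjusted p = 4.66e-05). IGFBP6, a binding protein of insulin-like growth factor, fell from 779 ± 350 to 217 ± 89.4 CPM (log2 -1.87, SE 0.27, adjusted p = 0.000346), and both fell in 12 of 12. Within V1 and V2 the changes were 3.28 and 2.85 for ADAM12, 2.66 and 2.31 for COL8A1, -2.10 and -2.39 for LEPR and -1.77 and -1.94 for IGFBP6.

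Other large rises in fibroblast-like cells were those of the chitinase-like protein gene CHI3L2 (log2 3.38, SE 0.74), DEPP1 (3.28, SE 0.59) and the basement membrane collagen COL4A4 (3.19, SE 0.66). The matrix metalloprotease MMP11 (3.11, SE 0.58), the potassium channel KCNJ15 (3.08, SE 0.61) and the matrix glycoprotein tenascin-C (TNC, 2.43, SE 0.60) rose too. So did the non-coding RNA LINC00968 (2.27, SE 0.41), the sphingosine kinase SPHK1 (2.21, SE 0.45) and the lactate exporter SLC16A3 (2.20, SE 0.42). Their adjusted p ran from 0.00302 for LINC00968 to 0.0246 for TNC, and 10 to 12 of the 12 SSc biopsies lay above the control mean. The other large falls were those of ELANE (-2.498, SE 0.44), C2orf40 (-2.36, SE 0.57), the caveolar protein gene CAVIN2 (-2.12, SE 0.45) and CAPS (-2.07, SE 0.35). The sodium channel SCN7A (-2.04, SE 0.58), CRTAC1 (-1.91, SE 0.43), MTSS1 (-1.78, SE 0.33), ENHO (-1.745, SE 0.47), the tetraspanin TSPAN7 (-1.73, SE 0.41) and the ferritin receptor SCARA5 (-1.68, SE 0.39) fell too. The adjusted p of these falls ran from 0.00211 for CAPS to 0.0409 for SCN7A. Of the genes fixed by name, COL1A1, the main chain of type I collagen, rose by 1.15 (SE 0.31, adjusted p = 0.0311), THBS1, which activates latent TGF-beta, by 1.70 (SE 0.35), POSTN by 1.24 (SE 0.26) and CTGF by 0.94 (SE 0.20). SFRP2, a Wnt antagonist, had a log2 change of 0.39 (SE 0.25, adjusted p = 0.362) and SFRP4, of the same family, 0.70 (SE 0.59, adjusted p = 0.521), with 1.82 within V1 and -0.01 within V2. WIF1, another Wnt antagonist, had means of 378 ± 190 CPM in control and 76.2 ± 123 in SSc (log2 -2.19, SE 0.82, adjusted p = 0.121). COL3A1 (0.60, SE 0.27), COMP (1.43, SE 0.48) and the smooth muscle actin gene ACTA2 (0.17, SE 0.45) did not pass, and the sign of ACTA2 turned to -0.06 within V1 and to -0.13 without the chemistry term.

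On GRCh38, in GENCODE release 29, all 365 genes chosen for naming were matched by identifier and the genes placed here are protein-coding. PRSS23 (ENSG00000150687) lies on chromosome 11 from 86791059 to 86952910, ADAM12 (ENSG00000148848) on chromosome 10 from 126012381 to 126388455 and COL8A1 (ENSG00000144810) on chromosome 3 from 99638475 to 99799226. LEPR (ENSG00000116678) lies on chromosome 1 from 65420652 to 65641559, IGFBP6 (ENSG00000167779) on chromosome 12 from 53097436 to 53102345, COL1A1 (ENSG00000108821) on chromosome 17 from 50183289 to 50201632. SFRP2 (ENSG00000145423) lies on chromosome 4 from 153780592 to 153789120 and SFRP4 (ENSG00000106483) on chromosome 7 from 37905932 to 38025695. CCL19 (ENSG00000172724) spans 34689567 to 34691277 and CCL21 (ENSG00000137077) 34709005 to 34710124 of chromosome 9. HSPG2 (ENSG00000142798) lies on chromosome 1 from 21822245 to 21937297, THY1 (ENSG00000154096) on chromosome 11 from 119417378 to 119424985 and IFITM3 (ENSG00000142089) on chromosome 11 from 319669 to 327537.

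Among the fixed gene lists, the myofibroblast and contractile list rose in fibroblast-like cells: 7 of its 19 measured genes were higher and 0 lower, or 10 and 0 adjusted over the list alone (camera, adjusted p = 5.02e-09, and adjusted p = 0.0237 with an estimated correlation). Its members TNC, COL8A1, ADAM12 and the membrane protein gene LRRC15 (log2 1.54, SE 0.26) rose, while ACTA2 did not pass. ADAM12 and SFRP4 in this list follow what the study named from these samples, so its count is not independent evidence of a direction either. Of 29 genes for fibrillar collagens and their assembly, 11 rose and 1 fell (18 and 1 adjusted over the list alone, adjusted p = 3.74e-10, adjusted p = 0.146 with an estimated correlation). They included COL6A3 (1.23, SE 0.24), the procollagen proteinase BMP1 (1.11, SE 0.18), its enhancer PCOLCE (0.97, SE 0.16) and the prolyl hydroxylase P4HA3 (1.95, SE 0.39). Of 22 matrix proteases and inhibitors, 9 rose and 0 fell (12 and 1 adjusted over the list alone, adjusted p = 6.47e-08, adjusted p = 0.133 with an estimated correlation), with the protease inhibitor SERPINE2 (1.84, SE 0.31) and the procollagen N-proteinase ADAMTS2 (0.96, SE 0.18). PRSS23 in that list also follows what the study named, so the same limit holds. Proteoglycan and elastic fibre genes moved both ways, 4 up and 3 down of 25 (10 and 5 adjusted over the list alone, adjusted p = 0.154, adjusted p = 0.0237 upwards in V2 biopsies alone). EMILIN1 (0.83, SE 0.17) and EFEMP2 (0.75, SE 0.17) rose, and the latent TGF-beta binding proteins LTBP4 (-1.67, SE 0.23) and LTBP3 (-0.62, SE 0.16) fell. Of 14 basement membrane genes 4 rose and 0 fell, with NID2 (1.48, SE 0.30) and SPARC (1.15, SE 0.25), or 5 and 0 adjusted over the list alone (adjusted p = 0.00556, adjusted p = 0.435 with an estimated correlation).

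Lists of signalling genes were tested in the same fibroblast-like cells. Of 26 cytokine and chemokine genes 5 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.000217, adjusted p = 0.435 with an estimated correlation). CCL19, which attracts lymphocytes (log2 2.00, SE 0.53), the cholesterol 25-hydroxylase CH25H (1.98, SE 0.49), the oncostatin M receptor OSMR (1.04, SE 0.23) and CSF1 (0.79, SE 0.22) were among them. Of 36 interferon response genes 5 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 0.00228, adjusted p = 0.514 with an estimated correlation), among them IFITM3 (0.88, SE 0.17), IFITM2 (0.65, SE 0.18) and STAT2 (0.57, SE 0.16). For secretion through the endoplasmic reticulum and the unfolded protein response, 4 of 26 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 0.000365, adjusted p = 0.435 with an estimated correlation). KDELR2 (0.69, SE 0.17) and KDELR3 (0.78, SE 0.20), which retrieve proteins to the reticulum, rose and the stress factor DDIT3 (-0.58, SE 0.15) fell. Of 25 transcription factors tied to SSc fibroblasts 6 rose and 0 fell (7 and 1 adjusted over the list alone, adjusted p = 0.0245, adjusted p = 0.141 with an estimated correlation). RUNX1 (1.33, SE 0.23), IRF7 (0.82, SE 0.24) and CREB3L1 (0.79, SE 0.24) rose, and FOSL2 (0.86, SE 0.27) and FOXP1 (0.44, SE 0.23) did not pass. Some of these factors had been named by the study from these samples, so their count is not independent evidence of a direction. In V2 biopsies alone the cytokine (adjusted p = 0.124), interferon (adjusted p = 0.303) and transcription factor lists (adjusted p = 0.142) did not pass, and the reticulum list did (adjusted p = 0.0153). Of 22 TGF-beta response genes 2 rose (8 up and 2 down adjusted over the list alone, adjusted p = 0.0724, adjusted p = 0.0419 upwards in V2 alone). Of the other lists, antigen presentation passed as up (adjusted p = 0.000124, 0.0199 in V2 alone), as did hypoxia (adjusted p = 0.0120), endothelial mesenchymal (adjusted p = 0.0216) and pericyte contractile genes (adjusted p = 0.0311), which did not pass in V2 alone (0.702, 0.0657 and 0.248). None of these other lists passed with an estimated correlation. The Wnt list had 0 of 22 genes past the test (adjusted p = 0.174). Keratinocyte transcripts (13 genes, 0 past the test, adjusted p = 0.179) did not pass either. Markers of dissociation stress did not pass in all biopsies (33 genes, 0 past the test singly, adjusted p = 0.977, adjusted p = 0.993 with an estimated correlation), but moved down in V2 biopsies alone (adjusted p = 9.996e-08).

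The median number of UMIs per fibroblast-like cell was 4766 ± 2076 in SSc and 3152 ± 1097 in control biopsies, a difference that did not pass (log2 difference 0.53, permutation p = 0.0630, adjusted p = 0.315). With that depth as a further term in the edgeR fit 79 genes passed, 78 of them among the 514. Of 57 genes chosen by the naming rule that had passed, 34 no longer did, COL1A1, CTGF, THBS1, POSTN, TNC and MMP11 included, while PRSS23, ADAM12, COL8A1, LEPR, IGFBP6, THY1 and RUNX1 passed. Leaving out 1 biopsy at a time gave 258 to 641 genes, with 264 without SSc 2, 258 without SSc 3, 305 without control 7 and 324 without control 9.

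**Figure D2:**
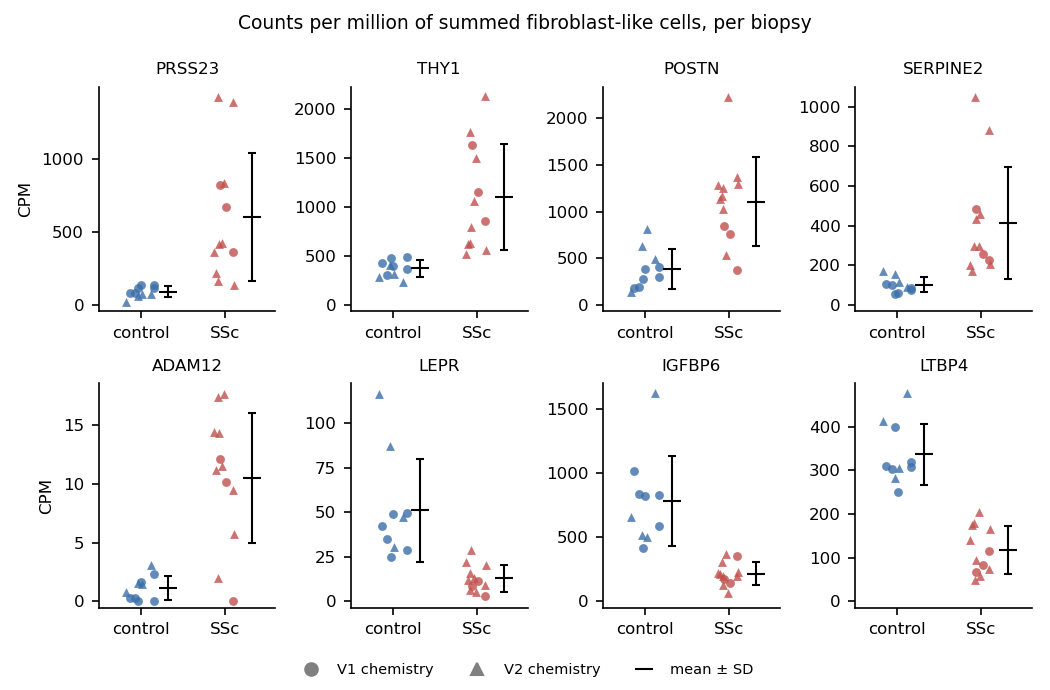
CPM (vertical axes) of 8 genes in the summed fibroblast-like cells of each biopsy; each point is 1 biopsy, circles are V1 and triangles V2 libraries, and bars give the mean ± SD (n = 10 control and 12 SSc). PRSS23 had means of 89.6 CPM in control and 601 in SSc, and LEPR 51.1 and 13.04.

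The share of fibroblast-like cells with at least 1 UMI of a gene was compared after each cell had been thinned to 1000 UMIs. PRSS23 was seen in 25.03% ± 12.4 of these cells in SSc (n = 12) and 6.29% ± 2.06 in controls (n = 10; adjusted permutation p = 0.00422), and CCL19 in 16.6% ± 7.22 and 5.71% ± 2.82 (adjusted permutation p = 0.00182). SFRP2 itself was seen in 59.3% ± 13.2 and 54.6% ± 10.97, a difference that did not pass (adjusted permutation p = 0.523). Cells with both SFRP2 and PRSS23 made up 16.1% ± 12.8 and 1.77% ± 0.661, and those with both SFRP2 and the Wnt antagonist WIF1 4.26% ± 6.14 and 13.98% ± 7.06 (adjusted permutation p = 0.0156 for each). Cells with both SFRP2 and SFRP4 made up 1.48% ± 1.06 and 0.471% ± 0.433 (adjusted permutation p = 0.0307). The shares with WIF1 (4.58% and 14.7%), with SFRP2 and no WIF1 (55.0% and 40.6%), with ADAM12 (0.855% and 0.0991%) and with COL8A1 (3.04% and 0.522%) passed as well, so that 9 of 13 measures did. Several measures share cells, and SFRP2, SFRP4, PRSS23, WIF1 and ADAM12 follow what the study named from these samples. The 9 are thus neither separate findings nor independent evidence of a direction. SFRP4 (2.33% and 1.76%), ACTA2 (5.77% and 5.38%) and the proliferation marker MKI67 (0.0255% and 0.0316%) did not pass. The MKI67 shares rest on 1 cell each in SSc 2, SSc 12 and control 7, and were 0.166% and 0.0339% in unthinned cells. A cluster led by cycling genes stayed unnamed and outside this class. These shares therefore do not decide whether fibroblasts cycle more in SSc.

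Within V1 (3 against 6 biopsies) the exact p was 0.0119, the smallest that 84 splits allow, for PRSS23, CCL19, COL8A1 and SFRP2 with PRSS23, whose differences were 17.4, 14.3, 1.36 and 13.5 points. Within V2 (9 against 4) the differences were 19.7 (exact p = 0.0182), 9.63 (exact p = 0.0406), 2.76 (exact p = 0.115) and 14.3 points (exact p = 0.0378). SFRP2 with WIF1 differed by -6.54 points within V1 (exact p = 0.202) and -11.9 within V2 (exact p = 0.0126), and SFRP2 with SFRP4 by 1.36 (exact p = 0.0357) and 0.765 points (exact p = 0.206). None of the 13 measures passed after adjustment in V2 alone. Thinning left out 540 of 6292 control and 389 of 5248 SSc fibroblast-like cells, which held fewer UMIs. In unthinned cells the shares were 47.5% and 13.9% for PRSS23, 23.6% and 7.70% for CCL19, 7.47% and 20.97% for WIF1, 4.02% and 1.46% for SFRP2 with SFRP4, and 67.1% and 61.7% for SFRP2. The share with both SFRP2 and SFRP4 did not pass in unthinned cells or in cells thinned to 2000 UMIs. As a background, thinned keratinocyte-like cells (median depth before thinning 6754 ± 2742 UMIs in SSc and 5555 ± 2545 in controls) showed PRSS23 in 0.972% and 0.674%, CCL19 in 1.06% and 1.23%, WIF1 in 0.993% and 0.161% and SFRP2 in 1.56% and 0.776%. ADAM12 was seen in 0.0951% and 0.0454% of them, COL8A1 in 0.516% and 0.187%, ACTA2 in 2.79% and 2.24% and MKI67 in 0.102% and 0.119%. An unnamed cluster led by the cycling gene UBE2C scored highest for keratinocyte markers. MKI67 in keratinocyte-like cells may thus be their own, and it gives no background for MKI67 in fibroblast-like cells. SFRP4 was seen in 0.00398% of keratinocyte-like cells in SSc, as a mean of the shares of the biopsies. In controls it was seen in 0 of 4364 cells of all biopsies together, which allows a share of up to 0.0687%.

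**Figure D3:**
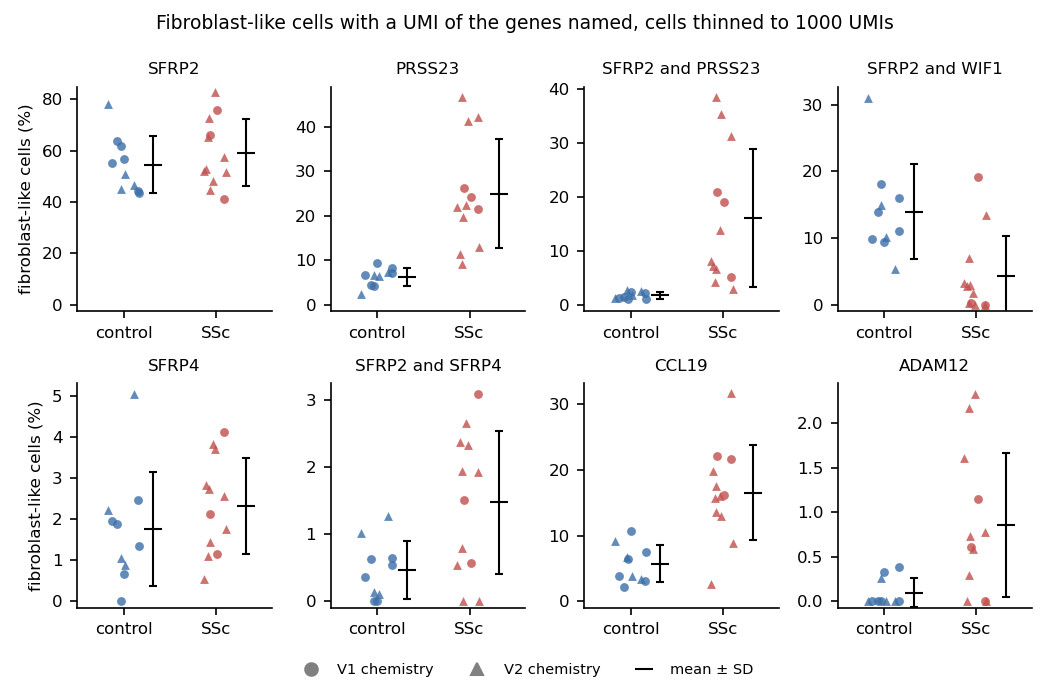
Percent of fibroblast-like cells with at least 1 UMI of each gene or gene pair (vertical axes), after thinning to 1000 UMIs per cell; each point is 1 biopsy, circles are V1 and triangles V2 libraries, and bars give the mean ± SD (n = 10 control and 12 SSc). SFRP2 with PRSS23 had means of 1.77% in control and 16.1% in SSc, and SFRP2 with WIF1 13.98% and 4.26%.

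Within SSc biopsies, fibroblast-like cells with both SFRP2 and SFRP4 UMIs were compared with those that had SFRP2 and no SFRP4 UMI, as a pair of sums per biopsy. As planned, with at least 10 cells of each kind, 2 biopsies qualified, and 6 genes were higher and 28 lower of 2990 tested with edgeR (260 at an unadjusted p under 0.05), while DESeq2 called 1. After thinning to 2000 UMIs, 5 biopsies qualified and gave 29 higher and 29 lower, and 11 of the 34 genes were called in both. In the planned fit the contractile genes ACTA2 (log2 2.92, SE 0.78) and TAGLN (2.34, SE 0.52), the matrix genes FN1 (1.59, SE 0.37) and LUM (0.71, SE 0.19), IGFBP3 (3.996, SE 0.49) and TNFSF18 (3.12, SE 0.55) were higher with SFRP4, in 2 of 2 biopsies. APOE (-2.27, SE 0.30), MT1X (-2.09, SE 0.30), CCL19 (-1.83, SE 0.37), PTGDS (-1.74, SE 0.23) and CXCL12 (-1.67, SE 0.35) were lower in both. With at least 5 cells of each kind, a minimum chosen after the count of cells was seen, 7 biopsies gave 7 higher and 10 lower genes of 751. MFAP5, a microfibril protein (1.86, SE 0.31), LUM (1.28, SE 0.16) and the small proteoglycan ASPN (1.45, SE 0.38) were higher in 7 of 7 biopsies, and TIMP3 (1.77, SE 0.42), FN1 (1.752, SE 0.30) and PRSS23 (1.25, SE 0.27) in 6 of 7. CTHRC1 (0.70, SE 0.20) was higher in 5 of 7. CXCL12 (-1.40, SE 0.25) was lower in all but 1, and MT1X (-1.53, SE 0.30) and CFD (-0.79, SE 0.20) in all 7. With at least 3 cells, 9 biopsies gave 10 higher and 3 lower of 320. In simulated counts of the planned size 0% of 2-fold and 25.5% of 4-fold changes were recovered, and 53.0% and 96.5% with 7 biopsies. The fitted log2 changes there were 1.45 and 1.41 times the set ones at the planned size and 1.09 and 1.06 times with 7 biopsies, so the folds printed from the planned fit are probably overstated. The median log2 difference of all genes was -0.30 in the planned fit, so the folds are relative to that shift, and cells without an SFRP4 UMI at this depth need not lack its transcript.

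The effect of SSc was then compared between fibroblast-like cells with and without an SFRP2 UMI in all 22 biopsies. For 14 genes it was more positive in SFRP2 cells and for 12 more negative, of 2618 tested (edgeR interaction term; 1 in V2 biopsies alone). The effects in each kind of cell come from separate fits, so their difference is not the interaction term. THY1, a surface protein of mesenchymal cells, rose by 1.83 in SFRP2 cells and had a change of 0.65 in the others (interaction 1.01, SE 0.19, adjusted p = 0.00372). SMOC2, a matrix protein gene, had 1.38 and -0.09 (interaction 1.31, SE 0.32, adjusted p = 0.0416), RARRES2, the precursor of chemerin, 1.06 and -0.03 (1.30, SE 0.23, adjusted p = 0.00292), and the chemokine gene CCL2 0.997 and -0.87 (1.61, SE 0.38, adjusted p = 0.0424). The circadian repressor BHLHE41 had -2.38 and -0.19 (-2.08, SE 0.47, adjusted p = 0.0188), and LTBP4 -1.79 and -0.83 (-1.06, SE 0.27, adjusted p = 0.0424). Tested alone, the SSc effect passed for 105 higher and 80 lower genes in SFRP2 cells and for 2 and 4 in the others. At an unadjusted p under 0.05 of the same edgeR fits there were 557 and 337 of 2618 genes. The other cells thus also held differences, and only the interaction term tests whether the 2 kinds of cell differ. With cells thinned to 500 UMIs 6 genes differed, and with no filter on low counts 61.

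Pericyte and smooth muscle-like cells of SSc skin had 282 genes higher and 145 lower of 7834 (edgeR). CCL21, a chemokine that draws CCR7-bearing lymphocytes and dendritic cells, rose from 16.8 ± 11.8 to 344 ± 366 CPM (log2 4.91, SE 0.75, adjusted p = 0.000706), in 12 of 12 SSc biopsies and by 4.55 within V1 and 5.23 within V2. CCL19, the other ligand of that receptor, rose from 204 ± 223 to 1130.2 ± 902 CPM (log2 2.88, SE 0.72, adjusted p = 0.0234; 10 of 12). THY1 rose by 2.504 (SE 0.29, adjusted p = 5.38e-05), the decoy receptor TNFRSF11B by 2.64 (SE 0.56), the cytokine IL32 by 2.44 (SE 0.55) and IGFBP2 by 2.37 (SE 0.32). ART3 (-2.42, SE 0.34), the zinc finger genes ZNF184 (-2.42, SE 0.36) and ZNF141 (-2.03, SE 0.37), the vesicle GTPase gene RAB3A (-1.92, SE 0.36) and ZNRD1 (-1.74, SE 0.39), which codes for a subunit of RNA polymerase I, fell in 12 of 12. The cluster with the largest share of the class differed between the groups. Cluster 5, led by RERGL and ACTA2, had 48.2% of it in controls and 41.4% in SSc, and cluster 6, led by RGS5 and RGS16 and with CCL19 among its 10 leading genes, 36.1% and 45.3%.

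Interferon response genes rose together in pericyte and smooth muscle-like cells, 12 of 30 with 0 lower (19 and 0 adjusted over the list alone, camera adjusted p = 1.48e-12, adjusted p = 0.133 with an estimated correlation). They included IFITM3 (1.21, SE 0.18), LY6E (1.61, SE 0.23), IFITM2 (1.19, SE 0.20) and IFI6 (1.57, SE 0.27). Of 10 complement genes 5 rose and 0 fell (6 and 0 adjusted over the list alone, adjusted p = 0.000124, adjusted p = 0.133 with an estimated correlation). C1R (2.25, SE 0.34) and C1S (1.93, SE 0.32), the proteases of the C1 complex, and their inhibitor SERPING1 (1.34, SE 0.25) did. Collagen genes rose in 11 of 25 cases and fell in 1 (17 and 1 adjusted over the list alone, adjusted p = 6.64e-09, adjusted p = 0.141 with an estimated correlation), with COL3A1 (1.497, SE 0.33), COL6A2 (1.06, SE 0.19), COL6A3 (1.21, SE 0.25) and PCOLCE (1.17, SE 0.18). Of 16 basement membrane genes 5 rose and 2 fell, with COL4A1 (1.598, SE 0.29) and COL4A2 (1.30, SE 0.21) among the rises (8 and 2 adjusted over the list alone, adjusted p = 0.00827, adjusted p = 0.422 with an estimated correlation). Cytokine genes rose in 3 of 22 cases (6 adjusted over the list alone, adjusted p = 0.000350, adjusted p = 0.435 with an estimated correlation). In V2 biopsies alone the basement membrane (adjusted p = 0.150) and cytokine lists (adjusted p = 0.116) did not pass. Lists tied to other cell types also moved up, with macrophage and dendritic activation (2 of 10 singly, adjusted p = 0.00420, 0.0274 in V2 alone) and capillary and arterial endothelial genes (2 of 10 singly, adjusted p = 0.0298, 0.248 in V2 alone). So did antigen presentation, endothelial mesenchymal, protease, lipid, reticulum, proteoglycan and transcription factor lists, with an adjusted p from 4.12e-05 to 0.0311, the last 2 of which did not pass in V2 alone (0.0515 and 0.338). None of these lists, the activation and the capillary and arterial ones included, passed with an estimated correlation. Fibroblast transcripts rose too, 4 of 10 with 0 lower (6 and 0 adjusted over the list alone, adjusted p = 0.000142, adjusted p = 0.373 with an estimated correlation), with COL1A2 (1.34, SE 0.30) and FBLN1 (1.28, SE 0.32). APOE (1.89, SE 0.37) and TIMP1 (1.53, SE 0.24) rose as well. The contractile list had 3 genes higher and 1 lower of 23 (3 and 4 adjusted over the list alone, adjusted p = 0.977), and the smooth muscle myosin MYH11 fell by 1.02 (SE 0.30, adjusted p = 0.0478). Its median log2 change was -0.15 and its mean 0.07. With depth as a term 303 genes passed, 268 of them among the 427, and of 30 genes chosen by the naming rule 5 no longer did, CCL19, IL32, FBLN1 and MYH11 included.

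Blood endothelial-like cells had 244 genes higher and 126 lower of 9829 (edgeR). HSPG2, the basement membrane proteoglycan perlecan, rose from 123 ± 17.4 to 253 ± 56.6 CPM (log2 1.08, SE 0.14, adjusted p = 7.61e-05) in 12 of 12 SSc biopsies, by 1.02 within V1 and 1.09 within V2. APLN, a peptide hormone gene of sprouting endothelium, rose by 3.28 (SE 0.73, adjusted p = 0.0177). The cell cycle genes CDKN3 (2.87, SE 0.59), TYMS (2.75, SE 0.63), TK1 (2.08, SE 0.52) and PCLAF (2.04, SE 0.56) and the adhesion molecule MPZL2 (1.98, SE 0.36) rose as well. The retinol carrier RBP4 (-2.59, SE 0.51), NEBL (-2.18, SE 0.41), the neurotrophin receptor NTRK2 (-1.62, SE 0.44) and TNMD (-1.56, SE 0.39) fell. PLAT, the tissue plasminogen activator (-1.45, SE 0.23, adjusted p = 0.00162), and the convertase PCSK5 (-1.40, SE 0.38) fell as well, PLAT in 12 of 12. Of 14 basement membrane genes 6 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 5.02e-09, adjusted p = 0.133 with an estimated correlation), with COL4A1 (1.41, SE 0.26), COL4A2 (1.38, SE 0.23) and SPARC (0.85, SE 0.17). Of 14 cell cycle genes 4 rose (7 adjusted over the list alone, adjusted p = 0.000401, adjusted p = 0.420 with an estimated correlation), BIRC5 (1.90, SE 0.37) and MCM5 (0.89, SE 0.26) among them. Of 25 collagen and assembly genes 4 rose (6 up and 1 down adjusted over the list alone, adjusted p = 0.000162, adjusted p = 0.422 with an estimated correlation), with the cross-linking enzymes PLOD1 (1.05, SE 0.21) and LOX (1.73, SE 0.40). Of 27 activation genes 3 rose and 3 fell (6 and 3 adjusted over the list alone, adjusted p = 0.464), and thrombomodulin (THBD, -0.73, SE 0.15) and CCL2 (-0.97, SE 0.27) were among the falls. Interferon response genes rose in 3 of 40 cases (3 adjusted over the list alone, adjusted p = 0.177), EPSTI1 (1.26, SE 0.29) and IFITM3 (0.58, SE 0.15) among them. Immediate early genes moved down as a list, with 0 of 33 past the test singly (adjusted p = 0.000403, adjusted p = 0.133 with an estimated correlation). Keratinocyte transcripts had a positive sign in 13 of 13 cases with a median of 0.55, 0 past the test singly (adjusted p = 0.00700, adjusted p = 0.615 with an estimated correlation). Without the chemistry term 213 genes passed, and without cluster 18, a deep cluster led by RGS5, 241 did. That cluster held 16.4% of the cells of the class in SSc and 21.3% in controls. Its median was 16412 UMIs per cell, against 2341 and 8370 in the other clusters, 7 and 13, so its part of the summed counts was larger. Of 26 genes chosen by the naming rule 17 still passed without it, 3 did not and the others were not tested. With depth as a term 357 passed, 342 of them among the 370, and of 26 genes chosen by the naming rule MCM5, PCLAF and CCL2 no longer did. Lists of reticulum, myofibroblast, pericyte contractile and endothelial mesenchymal genes passed as up (adjusted p from 0.00243 to 0.0457) and antigen presentation as down (adjusted p = 0.0224), and of these 5 the reticulum list passed in V2 alone (adjusted p = 0.0381). None of the 5 passed with an estimated correlation.

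**Figure D4:**
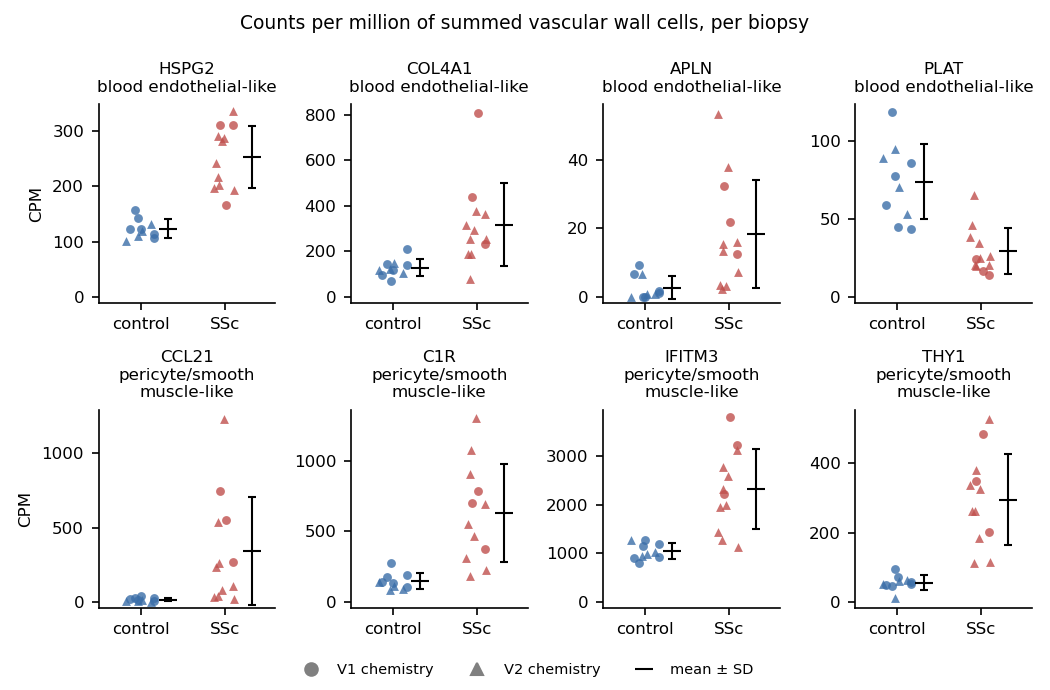
CPM (vertical axes) of 4 genes in blood endothelial-like and 4 in pericyte and smooth muscle-like cells, summed per biopsy; each point is 1 biopsy, circles are V1 and triangles V2 libraries, and bars give the mean ± SD (n = 10 control and 12 SSc). HSPG2 had means of 123 CPM in control and 253 in SSc, and CCL21 16.8 and 344.

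Macrophage and dendritic-like cells, with 11 SSc and 10 control biopsies, had 2 genes higher and 2 lower of 3278 (edgeR). The interferon-induced membrane protein genes IFITM3 (log2 1.52, SE 0.28) and IFITM2 (1.25, SE 0.22) rose, and SNN (-1.08, SE 0.20; adjusted p = 0.0106 for all 3) and the growth factor receptor FGFR1 (-1.58, SE 0.33, adjusted p = 0.0304) fell, each in 11 of 11. Of 16 interferon response genes 2 rose and 0 fell (9 and 1 adjusted over the list alone), and the list passed with the preset (camera adjusted p = 3.08e-09) and with an estimated correlation (adjusted p = 0.00736). IRF7 (1.01, SE 0.23) and IFI6 (1.92, SE 0.48) belong to it and did not pass over all genes. Cytokine genes moved up (adjusted p = 0.0428) and did not pass with an estimated correlation, nor in V2 alone (0.767, down). Their activation list did not pass (29 genes, 0 singly, 2 adjusted over the list alone, adjusted p = 0.132). With V2 biopsies alone 0 genes passed, with V1 alone 2, with free RNA subtracted 2 and with at least 50 cells per biopsy 15, and DESeq2 called 50.

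T and NK-like cells, with 10 biopsies per group, had 0 genes past the edgeR test of 2055 (143 at an unadjusted p under 0.05), while DESeq2 called 2. Among their fixed lists interferon response genes (0 of 13 singly, 3 adjusted over the list alone, camera adjusted p = 0.000946, adjusted p = 0.141 with an estimated correlation) and antigen presentation genes (0 of 18 singly, 5 adjusted over the list alone, adjusted p = 0.000162, adjusted p = 0.133 with an estimated correlation) moved up. The immunoproteasome gene PSMB9 had a change of 0.77 (SE 0.21), IRF7 of 1.09 (SE 0.32) and the invariant chain CD74 of 1.03 (SE 0.32). A macrophage and dendritic activation list also moved up, of whose 6 measured genes 4 were CD74 and HLA class II genes (0 singly, 3 adjusted over the list alone, adjusted p = 3.79e-06, adjusted p = 0.133 with an estimated correlation). Keratinocyte transcripts had a positive sign in 5 of 5 cases with a median of 0.89 (adjusted p = 0.0503, adjusted p = 0.525 with an estimated correlation). T cell activation genes did not pass (23 genes, 0 singly, adjusted p = 0.904). Their median log2 change was -0.06 and their mean 0.02.

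Keratinocyte-like cells had 0 genes past the edgeR test of 9811 (514 at an unadjusted p under 0.05), while DESeq2 called 1. In simulated counts of the same size 63.0% of 2-fold and 98.0% of 4-fold changes were recovered. The largest changes among named genes were those of the interferon-induced IFI6 (log2 2.46, SE 0.65, adjusted p = 0.911) and IFITM1 (2.11, SE 0.70), and of the stress keratins KRT6A (1.56, SE 0.86) and KRT16 (1.48, SE 0.71), none of which passed. As lists, interferon response (0 of 26 singly, 5 adjusted over the list alone, camera adjusted p = 0.00232, adjusted p = 0.463 with an estimated correlation), hypoxia and glycolysis (0 of 21, adjusted p = 0.000906, adjusted p = 0.422 with an estimated correlation) and secretion through the endoplasmic reticulum (0 of 24, adjusted p = 0.00281, adjusted p = 0.141 with an estimated correlation) moved up. In V2 biopsies alone the adjusted p was 0.00510 for interferon response, 0.973 for hypoxia and 0.0946 for secretion. Dissociation genes moved up (0 of 33 singly, adjusted p = 0.0216, adjusted p = 0.649 with an estimated correlation), but down in V2 alone (adjusted p = 0.0248). Antigen presentation (adjusted p = 0.0197) and cytokine genes (adjusted p = 0.0311) moved up and did not pass with an estimated correlation, nor in V2 alone (0.0627 and 0.626). The chaperone HSPA5 had 0.59 (SE 0.24). Stress genes (0 of 17, adjusted p = 0.0655, adjusted p = 0.000194 in V2 alone) and differentiation genes (0 of 20, adjusted p = 0.691) did not pass. Over the 6 classes 48 of 137 list tests passed with the preset correlation, and 2 with an estimated one: the myofibroblast list in fibroblast-like and the interferon list in macrophage and dendritic-like cells.

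**Figure D5:**
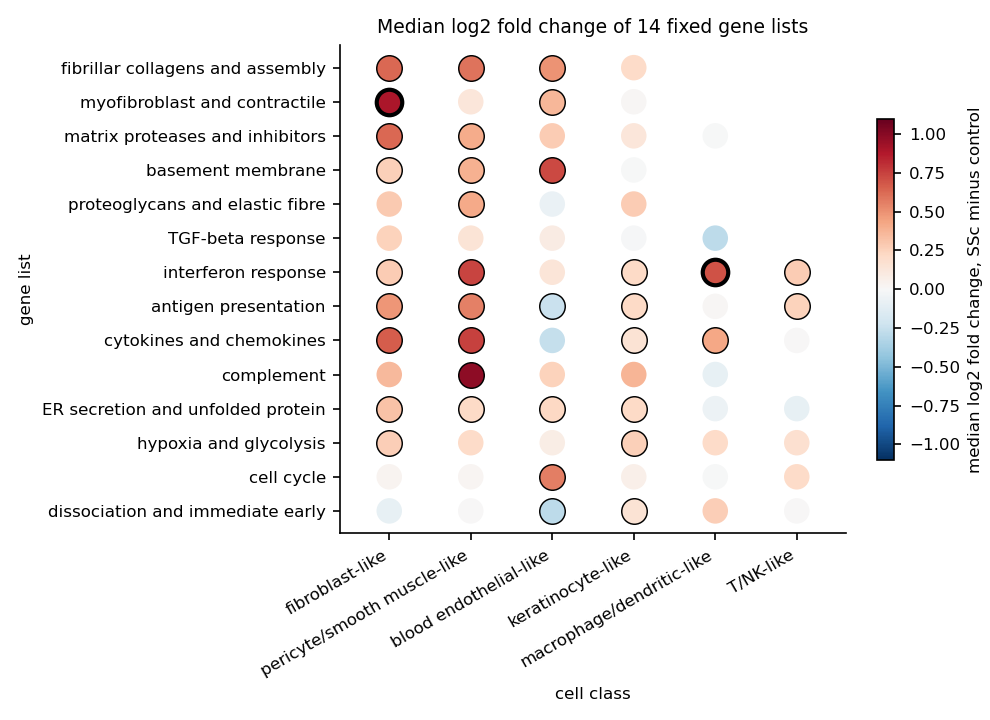
Median log2 fold change (colour, SSc minus control) of 14 fixed gene lists (vertical axis) in 6 cell classes (horizontal axis); a thin ring marks lists with adjusted p below 0.05 at the preset correlation, a thick ring those that also passed with an estimated correlation, and an empty place a list with under 5 measured genes. The 2 thick rings are the myofibroblast list in fibroblast-like and the interferon list in macrophage and dendritic-like cells.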

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

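Of the tests in this part, those of thinned cells, sub-clusters, the deep endothelial cluster, CCL19-rich fibroblasts and the mix of pericyte clusters were chosen after the result was seen. Depth as a term and free RNA subtracted were planned as alternatives, but their use as tests of an explanation was chosen then too, and the name of the pericyte pattern was reworded then too.

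The effect of SSc differed between SFRP2 and other fibroblast-like cells for 26 genes, by the interaction term of edgeR. It was more positive in SFRP2 cells for CCL2 (1.61), DIO2 (1.45), CYGB (1.38), SMOC2 (1.31), RARRES2 (1.30), LGALS3BP (1.08), GEM (1.04), THY1 (1.01), LAMA4 (0.999) and SRPX (0.94). It was more negative for BHLHE41 (-2.08), ENHO (-1.82), F13A1 (-1.56), LAMC3 (-1.43), CRIP2 (-1.17), CPE (-1.15), LTBP4 (-1.06), C9orf3 (-1.05), RSBN1L (-0.96) and ZBTB20 (-0.75). Of 60 splits of the biopsies 1, the real one, gave as many genes, and the highest other gave 1, so chance can be excluded. The number of splits was lowered from 100 to 60 to shorten the run, after the result with 100 had been seen.

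Single biopsies lay apart from the rest of their group of 10 or fewer by a gap of more than the critical share of the range (0.466 of it for 10 biopsies). In fibroblast-like cells these were control 3 for KCNJ15 (7.08 CPM, above the others), control 10 for PRSS23 (16.3 CPM, below) and control 6 for RUNX1 (8.39 CPM, below) and for NID2 (0 CPM, where a count of 0 allows up to 11.6). In blood endothelial-like cells control 5 had 0 CPM of TYMS (a count of 0 allows up to 4.22) and control 1 had 0 of PCLAF (up to 5.57). In pericyte and smooth muscle-like cells control 8 was low for THY1 (12.1 CPM) and control 3 for COL6A3 (20.3 CPM). In macrophage and dendritic-like cells control 2 was low for IFITM3 (52.4 CPM) and control 6 had 0 of FGFR1 (up to 45.1), and in T and NK-like cells SSc 8 was low for IRF7 (17.0 CPM). Control 8 had a high share of mast-like cells (2.06%), and control 7 high shares of fibroblast-like cells with SFRP4 (5.06%) and with MKI67 (0.317%). Control 10 had high shares with WIF1 (31.9%) and with SFRP2 and WIF1 (31.0%). Of 163 groups tested 16 held such a biopsy, and chance gives about 1 in 20, or 8.15. Groups of 11 or 12 biopsies, which include most SSc groups, were not tested, so these flags do not compare SSc with control.

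The 514 genes of fibroblast-like cells, COL1A1 and PRSS23 among them, could come from deep cells outweighing shallow ones in the sums, from a trend with the median UMIs per fibroblast-like cell of a biopsy, or from another mix of sub-clusters. In sums of thinned cells the median ratio of the log2 change to the reported one was 0.915 over the 300 of these genes that could be tested, and within sub-clusters 0.945 over 285. For those genes this argues against deep cells, and against a shift among these sub-clusters, as the whole cause, and the other genes are untested. The sub-clusters rest on components corrected by library, which brings the groups together, so another mix of cells within them stays open. Without that correction a fibroblast cluster led by COMP, with PRSS23 and THY1 among its leading genes, lay in 15 libraries. Of its cells 43.8% came from 1 library. With depth as a term the ratio was 0.863, and 78 of 514 genes passed. The median size of their log2 change fell from 0.82 to 0.70 while its standard error rose from 0.20 to 0.22, so calls ended through smaller folds and wider error in a fit with 1 more term, and depth stays open for part of the change. That term holds the UMIs of the fibroblast-like cells themselves, so it cannot tell sequencing depth from the RNA content of these cells. Of 100 splits 1, the real one, gave as many genes and the highest other gave 6, so chance can be excluded. The splits cannot tell SSc from other traits of the donors, and a change of the cells in SSc is untested beyond this.

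CCL21 and CCL19 in pericyte and smooth muscle-like cells could come from free RNA, other cells, another mix of clusters or a trend with depth. Keratinocyte-like cells of SSc held at most 0.0149 of their level, the median change of the lymphatic genes TFF3, which fell, MMRN1 and LYVE1 was 0.00127 of what lymphatic RNA would bring, and that of 5 fibroblast transcripts 0.0389 of what fibroblast RNA would bring, which argues against each. RNA of CCL19-rich fibroblasts could not bring CCL21, which had 0.0456 of the pericyte level there. As the source of CCL19 it would raise 5 fibroblast transcripts with it. DCN rose by 0.132 of that (95% bounds 0.0336 and 0.287) and LUM by 0.173 (0.0349 and 0.481), but COL1A1 by 0.810 (0.259 and 2.34), COL1A2 by 1.32 and COL3A1 by 1.06. The first rule for this test, with a median of 0.810 over the 5, left this source open, and the rule was rewritten after these values were seen. DCN and LUM argue against it as the whole source of CCL19, and the collagen transcripts leave it open in part. The SSc mix of the 3 clusters of the class, by UMIs, would at their control levels give 0.107 of the log2 rise of CCL21 (95% bounds 0.0427 and 0.181) and 0.186 of that of CCL19 (0.0813 and 0.295), which argues against a larger part of cluster 6 as the whole cause. With depth as a term CCL21 kept 0.772 of its log2 change (4.91, SE 0.75, to 3.796, SE 0.72) and passed (adjusted p = 0.00655), which argues against depth as its whole cause. CCL19 kept 0.805 (2.88, SE 0.72, to 2.32, SE 0.70) and no longer passed (adjusted p = 0.0688) because its fold was smaller, so a trend with depth stays open for CCL19. A change of the pericytes themselves, or of the mix within a cluster, stays open and untested. Of 100 splits only the real one gave 427 genes of this class (highest other 1), so chance can be excluded.

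The 370 genes of blood endothelial-like cells, HSPG2 and COL4A1 among them, may rest on cluster 18, which is deep and led by the pericyte gene RGS5, or on free RNA. Of the barcodes of that cluster 13.2% had been marked as doublets and left out, so other doublets may remain in it. COL4A1 and COL4A2 were among its leading genes. Without that cluster the median ratio of the log2 changes was 0.993 over the 329 of these genes that could be tested, and with free RNA subtracted 1.01 over 369. For those genes this argues against both as the whole cause, and the others are untested. A change of the vessels in SSc stays open as a hypothesis and untested. Of 100 splits only the real one gave as many (highest other 1), so chance can be excluded.

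For the other comparisons, 1 of 100 splits, the real one, gave 4 genes in macrophage and dendritic-like cells (highest other 1), so chance can be excluded at 1 in 20. For the gene lists 4 of 100 splits gave at least 48 (highest other 51), which is under 1 in 20 for the count as a whole. Since another split of the same biopsies called 51 lists, the count does not exclude chance for single lists called with the preset correlation. In keratinocyte-like cells and in T and NK-like cells 100 of 100 splits gave at least the real 0 (highest other 2 in each), as any split must, so these counts decide nothing. At an unadjusted p under 0.05, 31 of 100 splits gave as many as the 514 genes of keratinocyte-like cells, and 3 of 100 as many as the 143 of T and NK-like cells. With SFRP4 and at least 5 cells of each kind, 2 of 64 splits gave at least 17 genes, and the other one of these gave more than the real one (24). The minimum of 5 cells was chosen after the cell counts were seen, so this share does not exclude chance.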

How the results depend on the processing

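The sums of thinned cells, the fit without the deep endothelial cluster and the minimums of 5 and 3 cells with SFRP4 were chosen after seeing the data. No paired analysis was possible because the replicate numbers follow only the order of accession, and no label pairs an SSc with a control biopsy. Of the 514 genes of fibroblast-like cells, all that were tested kept their sign in every alternative. The alternatives refit the biopsies, or a part of them, in which these genes had been called, so kept signs are not independent evidence of a direction. The number of genes called was 920 with DESeq2, 22 in V2 and 29 in V1 biopsies alone, 79 with depth as a term, 181 in sums of thinned cells, and 258 to 641 with 1 biopsy left out. In blood endothelial-like cells it was 711 with DESeq2, 213 without the chemistry term, 63 in V2 (24 higher and 39 lower, where all biopsies gave 244 and 126) and 5 in V1 alone and 241 without the deep cluster. In pericyte and smooth muscle-like cells it was 655 with DESeq2, 53 in V2 (23 higher and 30 lower) and 40 in V1 alone (36 and 4), where all biopsies gave 282 and 145, and 303 with depth as a term. In macrophage and dendritic-like cells it was 50 with DESeq2, 13 without the filter, 0 in V2 and 2 in V1 alone, 15 with at least 50 cells and 2 with free RNA subtracted. In T and NK-like cells it was 2 with DESeq2, 44 without the filter, 1 with doublets kept and 2 with at least 50 cells, and in keratinocyte-like cells 1 with DESeq2. V1 and V2 alone hold fewer biopsies, and the cause of the other changes was not tested.

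For SFRP4 among SFRP2 cells 1 gene passed with DESeq2, 15 with RLE factors, 139 without the filter, 58 after thinning to 2000 UMIs, 17 with at least 5 and 13 with at least 3 cells. Without the filter the median of all genes shifted by -0.85 there. For the interaction 61 passed without the filter, 6 after thinning to 500 UMIs and 1 in V2 alone. None of the 13 measures of cells with a UMI passed in V2 alone (0, permutation test). Of the gene lists 2 passed with an estimated correlation and 26 with fry.

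The genes and shares given next changed sign, and none of them had passed its test. In fibroblast-like cells SFRP4 had -0.014 in V2 alone, and ACTA2 had -0.13 without the chemistry term and -0.059 in V1 alone. With 1 biopsy left out ACTA2 ran from -0.11 to 0.433, negative without SSc 1 (-0.09) and SSc 7. The difference in the share of T and NK-like cells was -0.931 with the other cell calling rule and -0.0397 on the logit scale, that of melanocyte-like cells -0.0239 and -0.0262, and that of pericyte and smooth muscle-like cells 0.0124 with that calling rule. That of blood endothelial-like cells was 0.338 among cells that are not keratinocyte-like, and that of mast-like cells 0.00295 without the chemistry term. The difference in the share with SFRP4 was -0.0272 in V2 alone, with ACTA2 -0.228 with doublets kept, and with MKI67 0.0300 after thinning to 2000 UMIs, 0.102 without thinning and 0.0283 with doublets kept. Of the called genes of blood endothelial-like cells 369 of 370 kept their sign in V1 alone, and of those tested with SFRP4 31 of 32 after thinning to 2000 UMIs. The direction of 4 lists that had passed turned to down in V2 alone. These were dissociation genes in keratinocyte-like cells (adjusted p = 0.0248), endothelial mesenchymal genes (adjusted p = 0.934) and pericyte contractile genes (adjusted p = 0.490) in blood endothelial-like cells, and cytokine genes in macrophage and dendritic-like cells (adjusted p = 0.767). Dissociation genes, which had not passed there, also turned to down in V2 alone in pericyte and smooth muscle-like cells (adjusted p = 0.0359) and in macrophage and dendritic-like cells (adjusted p = 0.00770). Of the lists that passed in neither fit, those that turned include keratinocyte differentiation in V2 alone (adjusted p = 0.0781), T cell activation in V2 alone (adjusted p = 0.491) and the pericyte contractile list with fry (adjusted p = 0.87). The cause was not tested. Thinning to 500 UMIs left 1 biopsy for SFRP4 among SFRP2 cells, no control biopsy qualified for that fit, and T and NK-like cells could not be fitted in V1 alone.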

Other observations

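The number of genes that differed was counted within fibroblast sub-clusters. A sub-cluster led by SAA1, STC2 and COMP, with PRSS23 and THBS1 among its leading genes, had 213 genes higher and 162 lower of 5709 in SSc (edgeR, 9 control and 10 SSc biopsies). The 2 sub-clusters with CCL19 and APOE markers had 68 higher and 24 lower (9 and 7 biopsies) and 17 and 7 (8 and 9). The papillary sub-cluster, with the Wnt antagonist APCDD1, had 34 and 22, and the PI16 and CD55 sub-cluster 30 and 22. The sub-cluster with SFRP4 and COL8A1 had 0 of 1214 past the edgeR test (81 at an unadjusted p under 0.05, 6 control and 5 SSc biopsies, DESeq2 not run). So did the 2 dermal sheath and papilla sub-clusters (0 of 1329 and 0 of 1335, 108 and 61 at an unadjusted p under 0.05, 8 and 8 biopsies each) and an unnamed one led by TNFAIP6 and IL6 (0 of 3510, 335 at an unadjusted p under 0.05, 3 and 3 biopsies). The 2 other unnamed ones tested had 9 higher and 4 lower (9 and 5 biopsies) and 11 and 2 (6 and 4). Whether these effects differ between sub-clusters was not tested.

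Among secretory gland-like cells the median number of UMIs per cell was 4566 ± 2439 in SSc (10 biopsies) and 1843 ± 1112 in controls (9 biopsies; permutation p = 0.00991, adjusted p = 0.0991), which did not pass. Of the cells in unnamed clusters, 44.1% in SSc and 35.1% in controls lay in the shallow cluster led by HBB and S100A8, and 20.9% and 18.7% in a cluster led by the cycling genes UBE2C, PCLAF and TOP2A. Keratinocyte markers were among the leading genes of the shallow cluster.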
